A study of Mus musculus with 4 samples.

How the data were processed

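Chromatin immunoprecipitation with an antibody against Deaf1, a DNA-binding transcription factor, was followed by sequencing in C2C12 cells, a mouse myoblast line that forms contractile myotubes in culture. Per the sample labels, the cells were myocytes (the series' description says differentiated myoblasts), crosslinked with formaldehyde, and the chromatin was prepared with an enzymatic digestion kit. The series has 4 samples, 2 of Deaf1 ChIP and 2 of input chromatin. Per the labels' protocols a control IgG was also used. Read files and signal tracks were not analysed here, and the inputs entered no comparison because only peak lists of the ChIP samples were used. The labels number the replicates but do not say whether they came from separate cultures, so their spread may be technical.

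Per the submitters' processing notes, BWA and MACS2 were used and the genome build was mm10. Versions, parameters and the control given to the peak caller are not given in the sources used here. The authors deposited a peak list for each ChIP replicate, so peaks were called per sample and not on pooled reads. The fold enrichment, a ratio of the signal at the summit to the background the caller estimated, is the authors' own value for each peak. The −log10 p-value and −log10 q-value of each peak are also the authors' deposited values. The deposited score equalled 10 times the −log10 p, rounded down, in 100% of peaks of both lists. The peak start, end and summit are deposited positions and were converted to 1-based coordinates. Fold, p and q were used to describe, rank or filter peaks within a list.

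The files give no read depth. Each peak's summit pileup (the number of fragments covering it) and local background were recovered by solving for the whole-number pileup that gives the deposited fold and p under a Poisson model, with 1 added to pileup and background. The largest misfit in −log10 p was 4.07e-05 in replicate 1 and 3.87e-05 in replicate 2. From the same model 2000 peaks were simulated, and among those within set limits of −log10 p this recovered 100% of pileups. The simulated backgrounds did not cover the full range of those in the lists. The lowest background was 2.13 fragments in replicate 1 and 1.64 in replicate 2, and 21.4% and 24.9% of peaks had a background raised above it by more than 0.003. Of these raised values 93.4% in replicate 1 and 92.9% in replicate 2 fell within 0.002 fragments of regular steps. The steps were multiples of a unit, 0.668 fragments in replicate 1 and 0.542 in replicate 2, or of that unit rescaled to a 1 kb window. Both kinds thus rest on the same unit, as counts of another library scaled by a constant would give. Multiples of the unit before rescaling alone held 63.4% and 57.7%. The lowest background divided by the shortest peak, 163 bp and 154 bp, gave replicate 1 an estimated depth of 1.23 times that of replicate 2. This estimate takes the shortest peak as the fragment length. For a single summit pileup only counting error can be given, since other variation between libraries cannot be estimated from a single list. The median pileup was 19 fragments in replicate 1 and 23 in replicate 2.

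The reference used here was a table of RefSeq gene spans of GRCm38.p6, the assembly behind mm10, without strand, transcription start sites, exons or sequence. The planned window around transcription start sites was therefore replaced by a window of 1 kb around either end of a gene's span. The span runs over all RefSeq models of a gene, predicted ones included. A gene end may thus be the start or the finish of transcription, and promoters inside a span are missed. The planned counts of the TTCG half-site and other motifs at summits, the exon and intron classes and the CpG-matched backgrounds were not run. Gene spans came from 21631 protein-coding genes on chromosomes 1 to 19 and X.

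A shared region was a block of overlapping peaks (at least 1 bp) from both replicates. Overlap was compared with 1000 circular shifts of the replicate 2 peaks within each chromosome, one-sided, and the share of shared regions at gene ends with 1000 shifts of the regions. A gene was called occupied when both replicates had a summit within 1 kb of the same end. The same-end rule was set after the files were opened and before any occupancy was computed. The 16 gene lists were written before the data were examined, and 720 of their 723 entries matched a gene in the table, 1 of them through a synonym. Each list was set against all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 16 lists, threshold 0.05. Genes are not independent replicates, neighbouring genes can share a peak, and 10 genes stood in more than 1 list. Intervals of shares are exact Clopper-Pearson intervals at 95%. In simulated data, with occupancy drawn separately for each gene, 4% of 200 random lists reached an unadjusted p under 0.05. Likeness among the genes of a functional list was not simulated, so this does not show how often such lists would pass.

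The genes named were fixed by rule before the data were examined. They were 10 set genes, up to 4 occupied members of each list with the best mean percentile of fold over both replicates, and the 10 best genes by that measure in the genome. The fold given for a gene is that of the highest peak of each replicate at the same gene end. The text gives a selection of the list members that the rule named. The values of 1 of them are not reported here. The alternatives tried were a −log10 q of 5 or more, a fold of 5 or more, the longer list shortened to the shorter, stricter overlap rules, windows of 500 bp, 2 kb and 5 kb, and each replicate alone. Others were added after seeing the data, namely summits at either end, regions anywhere in a gene, strata of gene density and gene length, and leaving out chromosome 15 or the olfactory and vomeronasal receptor genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.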

Results

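The data were lists of Deaf1 ChIP-seq peaks from 2 replicates of C2C12 myocytes, with 2 input samples that were not analysed here. The sample labels call the cells myocytes, while the series' own description speaks of differentiated myoblasts, so the stage of differentiation is not settled. Replicate 1 had 65606 peaks with a median width of 257 bp and replicate 2 had 26503 with a median width of 293 bp. The number of reads is not known from these files. Over all peaks of each list, the median fold enrichment was 6.07 in replicate 1 and 8.34 in replicate 2. These medians run over unlike sets of peaks. In the 2 lists 11 and 31 peaks had a q-value above 0.05. The comparisons asked where Deaf1 ChIP signal lay in both replicates, at which genes, and in which groups of genes. There was no second condition, so none of them compares biological states.

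Most Deaf1 ChIP peaks of replicate 2 overlapped a peak of replicate 1. By at least 1 bp, 94.0% of the replicate 2 peaks did so, against a mean of 2.20% and a highest value of 7.25% in circular shifts. Of the replicate 1 peaks, 35.0% overlapped a replicate 2 peak, against a mean of 0.901% in shifts. In this permutation by shifts both had p = 0.000999, the smallest that 1000 draws can give. The shifts do not keep the gathering of peaks at gene ends, given below. Lists that both gather there would exceed the shifts anyway, so this test does not show sites specific to Deaf1. The overlaps made 22880 shared regions with a median width of 542 bp, and in 83.2% of them the highest summits of the replicates lay within 100 bp. Across shared regions, which are not independent replicates, the fold enrichments correlated with a Spearman rho of 0.839. At these same regions the median fold was higher in replicate 1 (12.5) than in replicate 2 (9.48). Peaks found in replicate 1 without a partner, 42638 in number, had a median fold of 5.11, against 12.5 for those with one. When replicate 1 was shortened to the length of replicate 2, the share of its peaks with a partner was 76.6%.

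**Figure D1:**
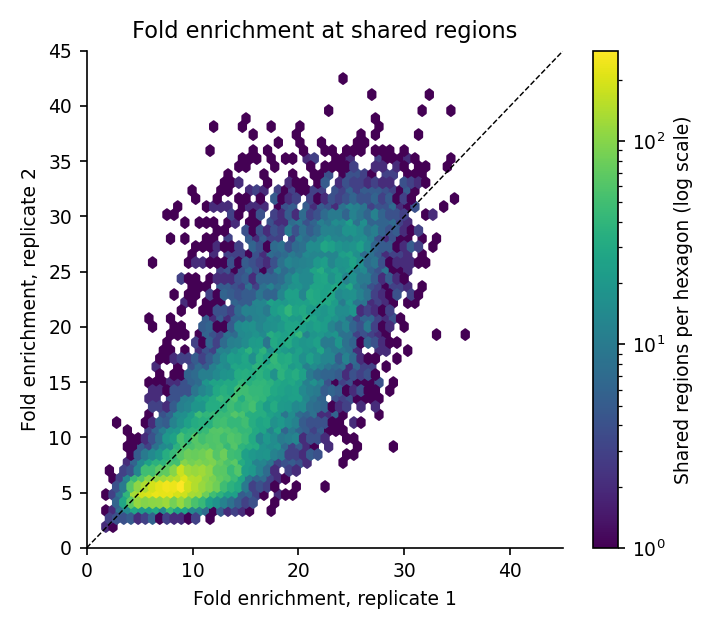
Fold enrichment over the caller's background at the highest peak of each replicate in the 22880 shared regions, replicate 1 on the x axis and replicate 2 on the y axis. Colour gives the number of regions per hexagon on a log scale, the dashed line marks equal values, and the Spearman rho across regions was 0.839.

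Shared Deaf1 regions gathered at the ends of protein-coding genes. Of the 22880 regions, 11272 (49.3%) lay within 1 kb of a gene end, 15.2 times the mean of circular shifts (3.24%, highest 6.95%, permutation p = 0.000999, the smallest that 1000 draws can give). Another 8694 (38.0%) lay deeper inside a protein-coding gene, ends of noncoding genes within it included. Of the rest, 688 (3.01% of all regions) lay within 1 kb of the end of a noncoding gene. The remaining 2226 (9.73%) lay elsewhere, where the inside of noncoding genes was not told apart from the space between genes. Regions within 300 bp of an end made up 32.0% of the total, and 81.1% of the regions within 1 kb lay on the inner side of the end. The fullest bin, with 2590 regions, ran from 100 to 200 bp inside the gene. A span reaches to the outermost of all RefSeq models and strand was not known. The inner side therefore need not lie downstream of the start in use. The share at gene ends was 21.2% in the weakest 10% of regions by fold and 77.8% in the strongest 10%. The share was 46.7% of all replicate 2 peaks and 25.8% of all replicate 1 peaks. The shifts keep only chromosome, width and spacing, and no peaks of a control were set against these regions. Signal common to promoters therefore cannot be told apart from binding by Deaf1 here.

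**Figure D2:**
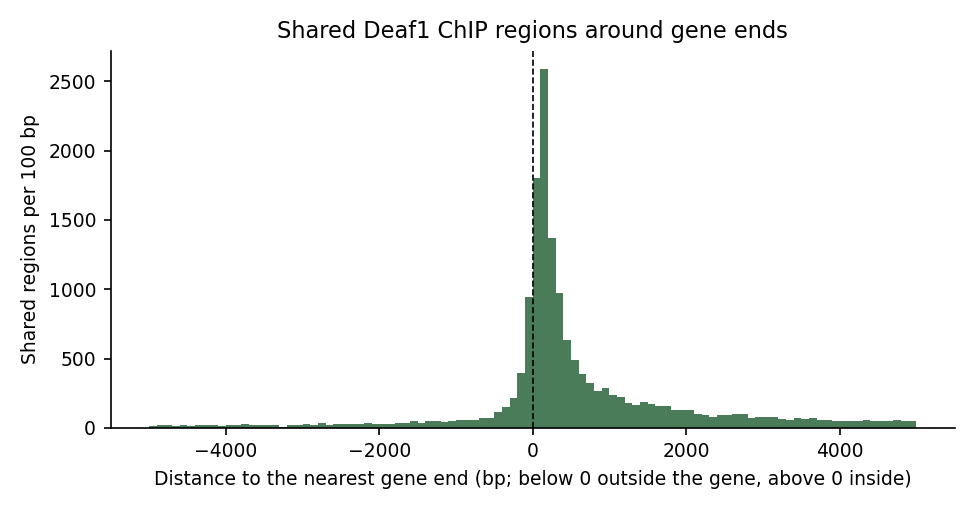
Number of shared regions per 100 bp bin (y axis) by distance in bp to the nearest end of a protein-coding gene (x axis), with values below 0 outside and above 0 inside the gene. The highest bin holds 2590 regions and lies 100 to 200 bp inside the gene.

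The strongest gene-end peaks stood at Zdhhc17, a palmitoyltransferase gene, with a fold of 32.2 in replicate 1 and 41.0 in replicate 2, and at Dip2c with 31.9 and 39.8. Arl8a, which encodes a GTPase of lysosome transport, had 31.6 and 37.5, and Ank, a pyrophosphate transport gene, had 34.7 and 35.3. Arf3, a GTPase gene of the Golgi, had 30.3 and 35.7. A single peak with folds of 30.0 and 36.0 on chromosome 4 (124850036 to 124851422) lay within 1 kb of 3 genes, namely Mtf1, which encodes a metal-responsive transcription factor, 1110065P20Rik and the tRNA modification gene Yrdc. Adgrl1, an adhesion receptor gene, had folds of 31.0 and 34.9, and Utrn, which encodes the dystrophin relative utrophin, 34.2 and 34.5. The region ranked first in the genome lay on chromosome 15 from 98634128 to 98635470, inside Cacnb3 and 6415 bp from the nearest gene end, with folds of 34.2 and 39.8. In all, 11164 of 21631 protein-coding genes (51.6%) were occupied, 893 of them at both ends.

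The Deaf1 gene itself had a peak at its higher-coordinate end on chromosome 7 (gene span 141297176 to 141338869). Its fold was 14.7 in replicate 1 and 4.55 in replicate 2, with summits 41 bp and 27 bp from the end, and Eps8l2 shares this peak. Its call ended when a fold or a −log10 q of 5 or more was required. Atg16l1, which encodes a protein of autophagosome formation, had a peak at its lower end on chromosome 1 (span 87756007 to 87792428), 181 and 190 bp inside. The pileups there were 60 and 51 fragments, and the folds were 5.89 and 13.3 over local backgrounds of 9.35 and 2.92. Pik3c3, the gene of the class III phosphatidylinositol 3-kinase (chromosome 18, 30265615 to 30348126), had no peak within 1 kb of either end in either replicate. Inside it, replicate 1 had 2 peaks with folds of 6.32 and 4.47, the former 7416 bp from the lower end, and replicate 2 had none.

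Hnrnpa2b1, an RNA-binding protein gene, had folds of 24.5 and 20.6 at an end from which Cbx3 is also within reach. Eif4g3, a translation initiation factor gene, was not occupied. Replicate 1 had a peak with a fold of 5.75 inside its higher end, 836 bp from it, where replicate 2 had none. Nearest to its lower end, peaks of both replicates lay 1867 and 1885 bp inside, with folds of 1.96 and 1.93 over backgrounds of 34.7 and 21.8 fragments. Mtor, the kinase of the growth-control complex mTORC1, was occupied at both ends. Its lower end on chromosome 4 (span 148448582 to 148557685) had folds of 12.9 and 17.1, and the peak beyond its higher end, shared with Exosc10, had 18.3 and 17.4. Foxo1 had folds of 25.9 and 21.8. At the higher end of Foxo3 the fold was 15.5 in replicate 1, with 24.0 in replicate 2 at the same position and 27.3 at a further replicate 2 summit inside the gene. The myogenic factor gene Myod1 had folds of 17.6 and 14.8. At Myog, another such gene, the peak found in both replicates lay outside the lower end with folds of 7.24 and 6.45, and replicate 1 alone had a higher peak inside the gene with a fold of 11.8.

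**Figure D3:**
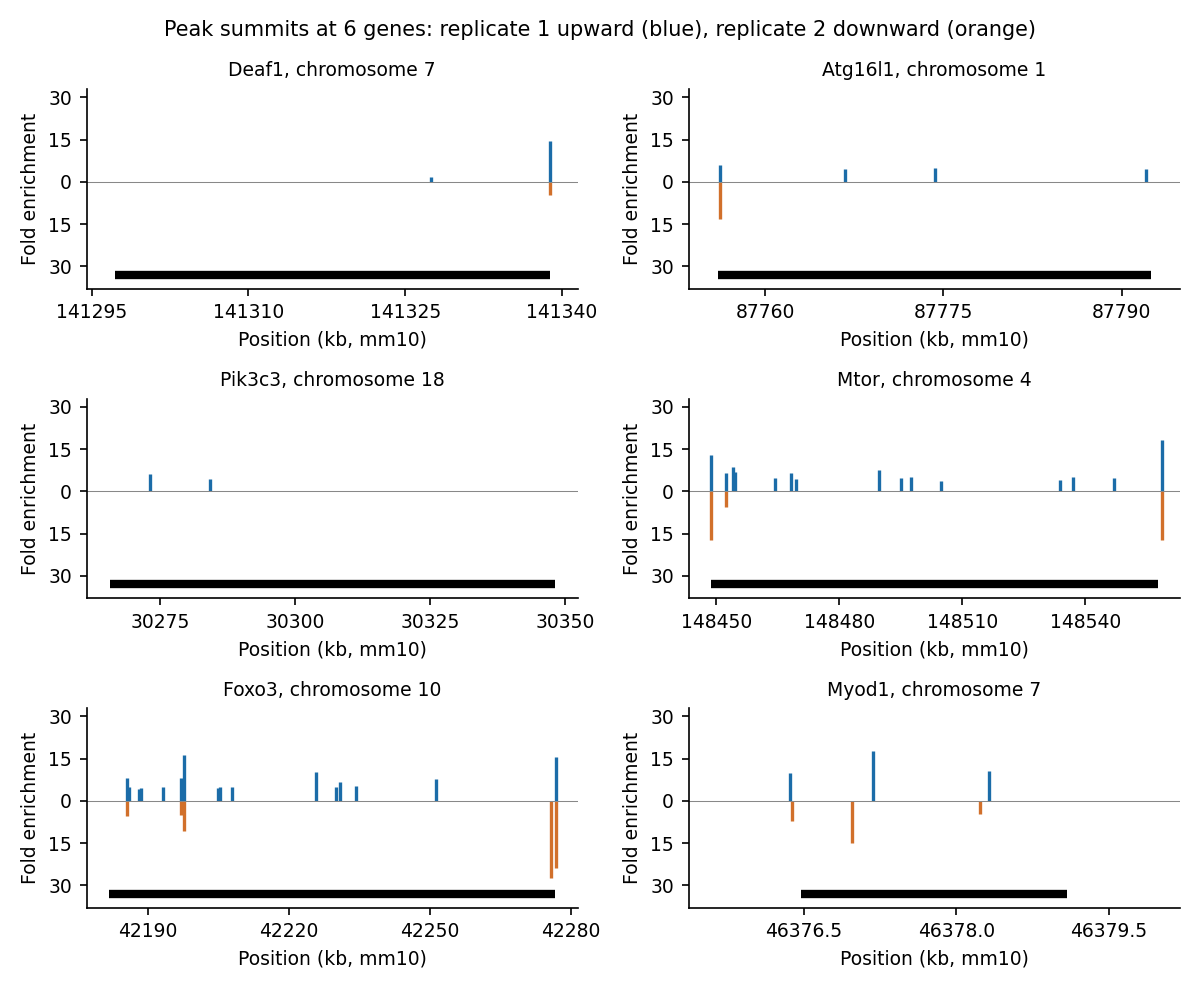
Peak summits within the spans of 6 genes and 1 kb beyond, by position in kb on mm10 (x axis) and fold enrichment (y axis), replicate 1 upward in blue and replicate 2 downward in orange. The black bar is the gene span, and Pik3c3 shows 2 peaks in replicate 1 and none in replicate 2.

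Genes of autophagy, mTORC1 signalling, the lysosome and the FOXO and muscle atrophy programme were occupied more often than other genes. In the autophagy list 31 of 40 genes (77.5%, interval 61.5% to 89.2%) were occupied, with an odds ratio of 3.24 (Fisher's exact test, adjusted p = 0.00198). Its highest members were Map1lc3a, which encodes the autophagosome marker LC3A, with folds of 31.2 and 34.5, Rb1cc1 with 29.1 and 28.6, Ulk2 with 30.3 and 22.7 and Wipi1 with 25.8 and 23.1. In the mTORC1 list 37 of 45 genes were occupied (odds ratio 4.35, exact test adjusted p = 0.000129). Examples were the folliculin partners Fnip2, with folds of 25.5 and 28.8, and Fnip1, with 23.9 and 26.9, and the mTORC1 activator Rheb, with 20.5 and 28.8. Of the lysosome and V-ATPase genes 40 of 45 were occupied (odds ratio 7.52, exact test adjusted p = 3.28e-06). These included Lamp1 with folds of 27.1 and 29.6, Atp6v1a with 25.2 and 26.5 at a peak shared with Naa50, and Tfeb, the transcription factor of lysosomal genes, with 24.0 and 26.9. Of the FOXO and atrophy genes 23 of 25 were occupied (odds ratio 10.8, interval 2.67 to 94.5, exact test adjusted p = 0.000129), among them Foxo6 with folds of 24.3 and 26.5, Fbxo31 with 24.6 and 25.8 and Sirt1 with 25.1 and 22.8. With replicate 1 alone the odds ratios were 11.8 for autophagy, 13.3 for mTORC1 and 13.3 for the lysosome. The lowest alternatives were 2.47 for autophagy in strata of gene length and 3.24 for mTORC1 with a 500 bp window. For the lysosome the lowest was 4.87 with a fold of 5 or more, and for FOXO 6.90 with a 500 bp window.

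Genes that most cells use for protein synthesis, protein breakdown, respiration, splicing and division were also occupied more often. Occupied members numbered 27 of 32 for the proteasome (odds ratio 5.07, exact test adjusted p = 0.00028), with Psmd11 at folds of 17.8 and 21.2. They numbered 35 of 42 for translation factors (odds ratio 4.70, exact test adjusted p = 0.000129), with Eif5 at folds of 23.2 and 35.7 and Eif3b at 25.5 and 25.8. Of cytosolic ribosomal protein genes 57 of 79 were occupied (odds ratio 2.44, exact test adjusted p = 0.000462), with Rpl14 at 26.8 and 27.7. Of oxidative phosphorylation genes 53 of 76 were occupied (odds ratio 2.17, exact test adjusted p = 0.00232), led by Cyc1, the cytochrome c1 gene, at 26.8 and 32.2. In the splicing list 44 of 56 were occupied (odds ratio 3.45, exact test adjusted p = 0.000132), with Hnrnpa3 at folds of 23.9 and 30.3. In the cell cycle list 44 of 57 were occupied (odds ratio 3.18, exact test adjusted p = 0.000241), with the cyclin E genes Ccne2 at 28.7 and 32.2 and Ccne1 at 26.5 and 29.6 and the retinoblastoma gene Rb1 at 21.4 and 32.2. With replicate 1 alone the odds ratios were 8.06 for translation factors, 4.28 for ribosomal proteins and 3.31 for oxidative phosphorylation. With a fold of 5 or more they were 3.15 for the proteasome, 2.96 for translation factors and 1.92 for ribosomal proteins. The lowest for oxidative phosphorylation was 1.86, without the olfactory and vomeronasal receptor genes. For splicing the odds ratios ran from 2.03 with a 500 bp window to 6.51 with a 5 kb window.

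Genes of the contractile apparatus and markers of other cell types were occupied less often than other genes. In the sarcomere and excitation-contraction list 16 of 54 were occupied (29.6%, interval 18.0% to 43.6%, odds ratio 0.394, exact test adjusted p = 0.00216). Its 4 highest members were Mylpf, a fast myosin light chain gene, with folds of 22.6 and 28.4, Cacnb1 with 21.4 and 22.4, Actn3 with 22.7 and 18.96, and the desmin gene Des with 22.0 and 17.4. The peaks at Mylpf, Cacnb1 and Actn3 were each shared with a neighbour, namely Tbc1d10b, Rpl19 and Zdhhc24. Of the markers of other cell types 17 of 63 were occupied (odds ratio 0.346, exact test adjusted p = 0.00026). Examples were Mbp, a myelin gene, with folds of 17.9 and 16.3, the germ cell gene Ddx4 with 16.6 and 14.0, and Cd4 with 20.1 and 18.6 at a peak shared with Gpr162. Neither lower rate held with replicate 1 alone, where 31 sarcomere genes (odds ratio 0.833, exact test adjusted p = 0.622) and 32 other-cell markers (odds ratio 0.637, adjusted p = 0.121) had a peak. A 5 kb window also ended the sarcomere call (odds ratio 0.925, exact test adjusted p = 0.833).

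Rates in the other 4 lists did not pass the test. Myogenic regulators and fusion genes were occupied in 20 of 29 cases (odds ratio 2.09, interval 0.907 to 5.20, exact test adjusted p = 0.0802), with Fst, the follistatin gene, at folds of 22.7 and 27.7 and Mef2d at 22.7 and 24.3. This list passed with a 2 kb window (odds ratio 2.43, exact test adjusted p = 0.0479), a 5 kb window (3.98, adjusted p = 0.0094) and replicate 2 alone (2.40, adjusted p = 0.0482). Fibroblast and adipogenic genes were occupied in 15 of 22 cases (odds ratio 2.01, exact test adjusted p = 0.158), with Cebpb at 29.4 and 34.9 and Pparg, the adipocyte nuclear receptor gene, at 25.5 and 30.7. Interferon and innate immunity genes were occupied in 17 of 39 cases (odds ratio 0.724, exact test adjusted p = 0.362), with Ifnar2 at 25.9 and 28.8, at a peak shared with Il10rb, and Tbk1 at 23.2 and 31.1, at a peak shared with Xpot. With replicate 1 alone 26 interferon genes had a peak and the odds ratio was 1.24 (exact test adjusted p = 0.622). Of 16 genes linked to Deaf1, among them Atg16l1, Pik3c3 and Mtor, 9 were occupied (odds ratio 1.21, exact test adjusted p = 0.805), with Rai1 at 26.2 and 31.1, Lmo4 at 27.5 and 29.5 and Gsk3a at 22.0 and 29.6. The odds ratio of this list ran from 0.816 with a fold of 5 or more to 1.96 with regions anywhere in the gene. The list includes Deaf1 itself and was not defined as one of binding targets, so its result does not test known targets.

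**Figure D4:**
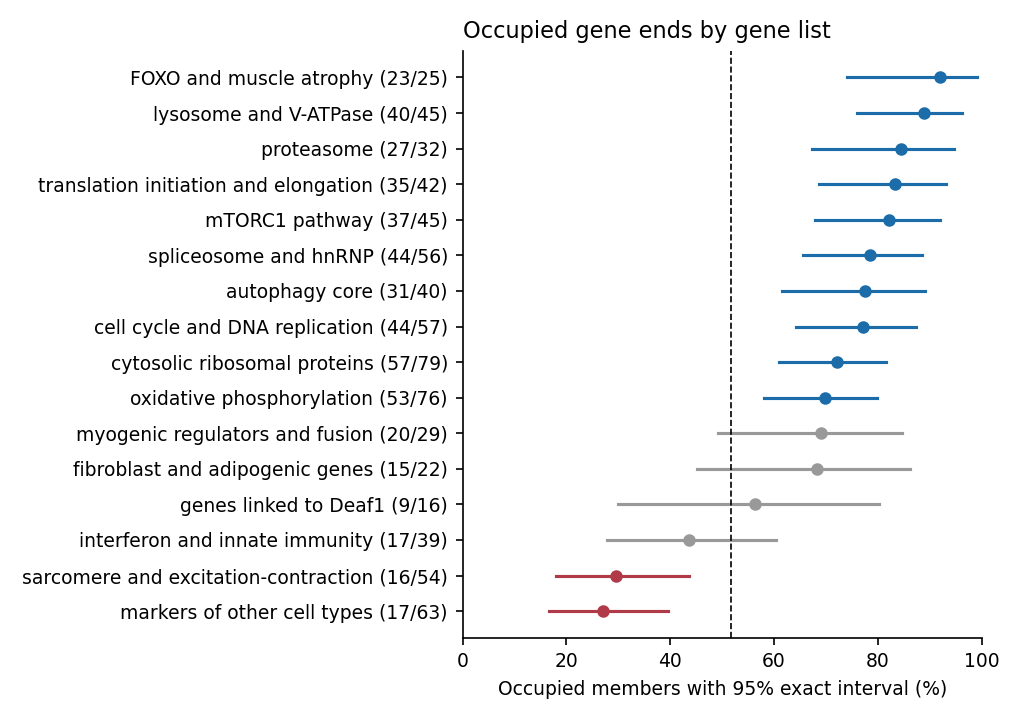
Percent of the members of each of 16 gene lists that were occupied (points) with 95% exact intervals (lines), occupied and total members in brackets. The dashed line marks 51.6% of all protein-coding genes, blue lists were higher and red lists lower at an exact test adjusted p under 0.05, and grey lists did not pass.

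The local background behind the peaks differed between chromosomes. On chromosome 15, 44.7% of replicate 1 peaks (interval 43.3% to 46.2%) and 42.7% of replicate 2 peaks (interval 40.4% to 45.0%) had a background above the lowest level. The next chromosome was 10, with 28.6% and 31.0%. Of the genes named above whose peaks lie on chromosome 15, Arf3 and Cyc1 had backgrounds of 2.13 and 1.64 fragments, the lowest of each list, and Ank had 2.29 and 1.92. The translation genes Eef1d and Eif4b, also named by the rule, had higher replicate 1 backgrounds there, 4.01 and 2.50. In replicate 2 theirs were 1.67 and 1.64. Intervals cover counting error only.

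**Figure D5:**
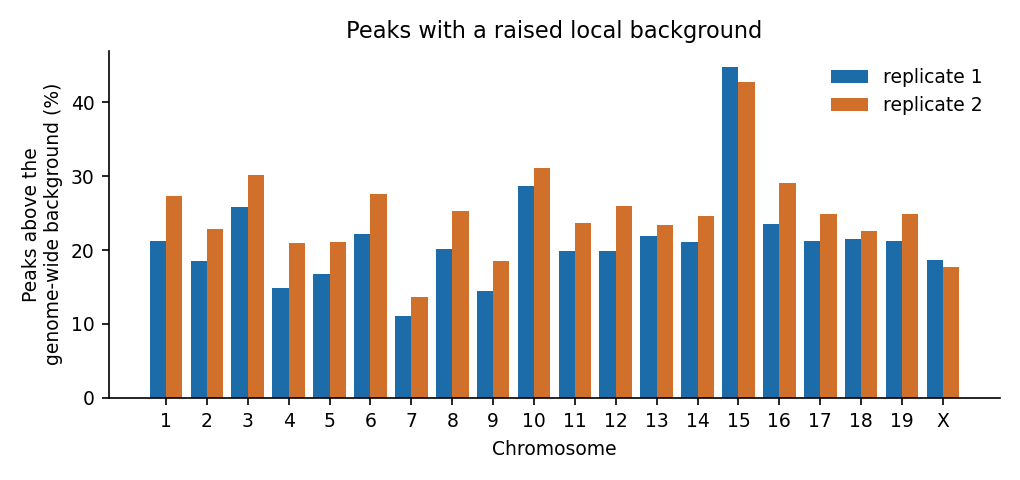
Percent of peaks whose local background exceeded the lowest background in their list (y axis), by chromosome (x axis), for replicate 1 in blue and replicate 2 in orange. Chromosome 15 is highest in both, at 44.7% and 42.7%.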

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

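Peaks on unplaced or unlocalised sequence, which entered none of the comparisons, were singled out because signal appeared outside the main measurement. Replicate 1 had 24 such peaks on 6 sequences and replicate 2 had 18 on 6, with median folds of 5.11 and 5.29. Replicate 2 also had 3 peaks on the mitochondrial genome with folds of 1.87 to 2.57, and replicate 1 had 0. No control list was used to set these against, and no biological explanation was tested.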

How the results depend on the processing

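No paired analysis was possible because the input samples share replicate numbers with the ChIP samples but gave no peak list to compare. The either-end, anywhere-in-gene, stratified, receptor-free and chromosome 15 settings were chosen after seeing the data. The 10 lists with higher occupancy kept their direction and stayed past the threshold in all 14 alternatives; the highest adjusted p among these was 0.0197 for autophagy. With a 5 kb window or regions anywhere in the gene all 25 FOXO genes were occupied, which gives no finite odds ratio (adjusted p 2.95e-05 and 6.61e-05). The myogenic list, not called in the main setting, passed with a 2 kb window (odds ratio 2.43), a 5 kb window (3.98) and regions anywhere in the gene (4.10), and its odds ratio ran from 1.62 to 2.40 over the single replicates (adjusted p 0.0055 to 0.407 over all alternatives). The sarcomere list lost its call with a 5 kb window (0.925) and ran from 0.456 to 0.833 over the single replicates, the higher value with replicate 1 alone. The list of other cell types ran from 0.364 to 0.637, again with the higher value from replicate 1 alone. Of the lists not called, interferon turned direction with replicate 1 alone (0.705 to 1.24 over the single replicates). The genes linked to Deaf1 turned with a −log10 q of 5 or more (0.994), a fold of 5 or more (0.816), equal list lengths (0.988) and strata of gene length (0.975), with adjusted p from 0.31 to 1 over all alternatives. The cause was not tested in any of these. The count of occupied genes ran from 9353 (500 bp window) to 13366 (replicate 1 alone). Of 82 named genes, 64 had the same call in all 10 occupancy settings. Of the 18 that changed, Deaf1 lost its call with a fold or a −log10 q of 5 or more and Eif4g3 gained one with the wider windows, with replicate 1 alone and with regions anywhere in the gene. The others lost theirs with a 500 bp window, namely Hnrnpa2b1, Foxo1, Ulk2, Lamtor2, Eif4b, Ndufa13, Hnrnpa3, Hnrnpab, Ccne2, Cdh2, Mef2d, Cacnb1, Actn3, Irf5, Rai1 and Cd4. The share of replicate 2 peaks with a partner was 84.0% at equal list lengths, 73.0% with summits within 100 bp and 69.2% with reciprocal overlap of 50%. The alternatives on motifs, CpG content and a single start site per gene were not run, since they need sequence or strand. Weak peaks limit what can be seen, since a replicate 1 peak inside Mtor with a fold of 3.51 rests on 10 fragments, and a gene without a peak is not shown to lack Deaf1.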

Other observations

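The receptor-gene rates, the gene body shares, the strength comparisons and the tests of lower enrichment, of chromosome 15 and of the pooled lists were chosen after the data had been seen.

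Olfactory and vomeronasal receptor genes, which are silent in most tissues, were rarely occupied. Of 1465 such genes 3 had summits of both replicates within 1 kb of the same end (0.205%, interval 0.0423% to 0.597%), namely Olfr1344, Olfr94 and Vmn1r4. Peaks of a single replicate and peaks deeper inside these genes were not counted. Among occupied genes, the proteasome list had a median fold percentile of 67.8, against 81.2 for the other occupied genes (permutation test, adjusted p = 0.0198). Oxidative phosphorylation genes stood at 70.4 (permutation test, adjusted p = 0.0136), ribosomal protein genes at 72.9 (adjusted p = 0.029), myogenic regulators at 69.5 (adjusted p = 0.0469) and sarcomere genes at 66.6 (adjusted p = 0.0337). The autophagy, mTORC1, lysosome and FOXO lists stood at 85.7, 83.9, 77.5 and 85.1 and did not pass this test.

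Peaks away from gene ends gathered inside genes, genes with an occupied end included. Of the 37005 replicate 1 peaks without a partner and more than 1 kb from an end, 72.1% lay inside a protein-coding gene, against a mean of 40.6% in circular shifts. Inside genes with an occupied end lay 54.6%, against 25.7% (permutation p = 0.000999 for both, the smallest that 1000 draws can give). For shared regions away from ends the shares were 74.9% and 51.6%, and for the 1512 unpartnered replicate 2 peaks 54.4% and 37.4%. Mtor and Foxo3 show this, with replicate 1 peaks spread along the gene.

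Replicate 1 had 2.48 times the peaks of replicate 2. Thinning replicate 1 to the estimated depth of replicate 2 left 2.36 times as many peaks, so depth alone does not account for the gap. Lower enrichment in replicate 2 stays open, since thinning by the excess pileup at the strongest shared regions (2.46 times as many left) is milder than thinning by depth and could not have ended the gap. Over all shared regions the median pileup of replicate 2 was 0.696 of that of replicate 1, below the estimated depth ratio of 0.812. By fold this ratio was 0.643 in the weakest 10% of regions, 0.5 in the next 10% and 0.930 in the strongest 10%. The strongest regions thus stood above the estimated depth ratio, and lower enrichment of replicate 2 was not seen there. Thinning by these ratios was not tried. Away from gene ends the extra peaks were not gathered in gene-dense blocks, where the ratio between replicates was 0.916 of that elsewhere. Loss of weak sites near the calling threshold of replicate 2 also stays open: unpartnered replicate 1 peaks had a median fold percentile of 33.3, and 13.2% lay at gene ends against at most 4.61% in shifts.

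On chromosome 15 the background was raised even at peaks more than 5 kb from any gene end, in 43.5% of replicate 1 and 37.5% of replicate 2 peaks, against at most 24.2% and 24.5% on another chromosome. Gene density does not account for the raised background over all peaks, where chromosome 15 stood at 44.7% in replicate 1 and the highest of the 11 chromosomes with more gene ends per Mb reached 28.6%. Peaks were also dense on chromosome 15, with 44.9 per Mb in replicate 1 and 17.2 in replicate 2. Only chromosome 11 had more, 51.4 and 19.1, and it has 26.4 gene ends per Mb against 14.9 on chromosome 15. A candidate explanation for the raised background is extra copies of chromosome 15 in these cells, which would raise a control library over its whole length. Copy number was not measured here, so this stays a hypothesis.

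The autophagy, mTORC1, lysosome and FOXO lists pooled were occupied in 128 of 152 genes, against 216 of 285 genes of the proteasome, ribosome, translation, respiration and splicing lists (odds ratio 1.70, interval 0.997 to 2.98, Fisher's exact p = 0.0493). Over this and 10 other settings p ran from 0.00673 to 0.222, so signal common to promoters of widely expressed genes cannot be told apart from a preference for these pathways. The occupied genes of the former lists had a median fold percentile of 84.0 against 73.8 (permutation p = 4e-05), but against all other occupied genes none of the 4 lists passed the test given above. Counting regions anywhere in the gene gave an odds ratio of 1.73 (interval 0.937 to 3.33); since the main interval already included 1, this could not show whether gene ends in place of start sites matter, and the reading of that test was changed to undecided after its value was seen.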
